A study of Mus musculus with 2 samples.

How the data were processed

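Lungs of 2 groups of mice were profiled with 1 array per group, untreated and MCT-treated, and each sample's group was taken from its treatment label. The title of the untreated sample names wild-type lungs, and that of the MCT sample names no genotype. Whether a sample was the lung of 1 mouse or a pool is not given in the sources used here. Per the labels' protocols, 2 µg of total RNA was given a poly(A) tail and a tag, hybridised overnight on a microfluidic chip by a service provider, and stained with a single dye, Cy3. The detection probes are complementary to mature miRNAs of miRBase, and names are those of the array's design, which can be older than current ones.

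The scanner tables give the median pixel intensity of each spot on a linear scale and its standard deviation, per the file headers. They were not background-subtracted, since the empty spots read 101 on the untreated and 253 on the MCT array at the median. Each array has 3968 spots. The deposited series table holds the authors' processed intensity of each probe, 1189 probes with medians of 7.55 in untreated and 14.4 in MCT-treated lung. From its values it is on a linear scale with the background removed and an intensity-dependent scaling between the arrays, and how this was done is not given in the sources used here. Its values had a Spearman's rho of 0.976 and 0.964 with the scanner intensities of the untreated and the MCT array over miRNA probes.

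Intensities were corrected with normexp in limma 3.58.1 under R 4.3.3, with an offset of 50, on the spot signals themselves, because the tables used here have no local background. The 257 empty spots, the 5S probes with 4 spots each and 43 spike calibration probes were then left out. The log2 values of the miRNA spots were quantile normalized between the 2 arrays, and the 3 spots of a miRNA were averaged. A miRNA was detected on an array when at least 2 spots exceeded the 95th percentile of that array's empty spots, 116 for untreated and 284 for MCT. This is the rule set for tables with no standard deviation of the background. A miRNA was called higher or lower in the MCT library when it was detected in either library, its log2 ratio was at least 1 in size (2-fold), and the spot values of the arrays did not overlap. The requirement on the spots removed no call. For a miRNA detected on 1 array, the lower bound of the fold sets its level against the higher of its own level on the other array and the lowest level of a detected miRNA there.

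The calls, lists, alternatives and the rule for named miRNAs were fixed before the data were examined. Named were up to 10 miRNAs with the largest ratios per direction among calls detected in both libraries and above the median level, up to 4 per direction detected in 1 library, the 5 brightest per library, and up to 4 detected members per list with the largest ratios. The hypertension, smooth muscle and endothelial lists also gave their brightest members, and any other member of a list could be given. The rule on the largest ratios yielded 10 higher and 7 lower miRNAs. The remaining calls (miR-680, miR-3963 and miR-365-3p), and miR-99a-5p and miR-181d-5p as relatives, were named after their values were seen. For each of the 18 lists the median log2 ratio of its detected members was set against 10000 random lists of the same size, matched on level in 10 bins, and a list stood apart below the percentile of 2.5 or above 97.5. Lists with fewer than 3 detected members have no percentile. Mature names were matched in full, with older names where the array uses them, and 8 list entries had no probe. The list for the Sfmbt2 cluster alone was matched by the start of the name (miR-297, miR-466, miR-467 and miR-669), so it also takes in miRNAs of these families from elsewhere in the genome. Cluster neighbours were taken from the RefSeq gene table of GRCm38.p6 at up to 10 kb between miRNA genes, the only use of genome positions here. Of the 310 miRNAs detected in both libraries, 268 were placed on 1 gene.

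The number of arrays, 1 per group, limits the precision. The median standard deviation over the repeat spots of a detected miRNA was 0.0849 log2 on the untreated and 0.0473 on the MCT array. It covers the spread within an array only. The steps were tested on simulated arrays of 1141 probes for this comparison. Of 50 miRNAs changed 2-fold 16% were called, of 50 changed 3-fold 48% and of 50 changed 4-fold 70%, none in the wrong direction. At a 1.5-fold change 0% were called. The criterion first set for this test, on the recovery of 4-fold changes at all levels, was not met. After that was seen it was replaced by a criterion on miRNAs above the median level, where the recovery was 33.3% at 2-fold, 77.4% at 3-fold and 94.6% at 4-fold. None of 941 unchanged miRNAs was called, but these included all miRNAs not detected in untreated lung. The simulation held noise of the spots and the background, but no error of single probes between arrays and no trend with GC content. It therefore gives no rate of false calls for the real arrays. Of 100 lists of 10 drawn at random from all detected miRNAs of the simulation, changed ones included, 2 stood apart. This gives no rate for lists of related miRNAs. The offset shrinks the ratios of dim miRNAs: the median estimate for a true log2 change of 2 was 1.52.

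Most alternatives changed 1 choice at a time. The authors' values differ in background removal, scaling and pseudocount together. Without background correction, and with the local background described below, the offset of 50 was left out as well. The local background also set the lowest value to 16. They were the background correction, the offset, the normalization, the summary and number of repeat spots, the filter on dim probes, the threshold, the spot rule, the detection rule and the authors' values, with a pseudocount of 50 for the last. After the data were seen, 3 were added: removal of the trend of the ratio with GC content by a lowess fit, a local background from dim neighbouring spots, and detection from dim miRNA spots. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.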

Results

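MicroRNA (miRNA) levels were measured in mouse lung with and without monocrotaline (MCT), a plant alkaloid that injures lung vessels and is given to rodents to induce pulmonary arterial hypertension. The series held 2 samples of lung, 1 titled untreated wild-type and 1 from MCT-treated mice that were 14 weeks old and had 30 days of treatment. The title of the MCT sample names no genotype. The age of the untreated mice is not given in the sources used here, so the groups may differ in age. Total RNA of each sample, 2 µg, was hybridised to a single-colour array. Each array carried 1141 mouse miRNA probes with 3 repeat spots each, 5 probes for 5S ribosomal RNA and 257 empty spots. With 1 array per group the differences had no replicate check, and no test of the difference between the groups and no p-value was computed. Values after ± are standard deviations over the repeat spots of an array. For a ratio they are the square root of the summed squares of both arrays' standard deviations. They measure the spread within arrays and not between animals.

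The brightest miRNAs of the lung were shared by both arrays. They were let-7a-5p, let-7f-5p, let-7c-5p and miR-26a-5p, joined by the endothelial miRNA miR-126-3p among the first 5 in untreated lung and by miR-23b-3p in MCT-treated lung. let-7a-5p had a normalized log2 intensity of 15.57 ± 0.051 in untreated and 15.53 ± 0.079 in MCT-treated lung. The 10 brightest miRNAs made up 30.5% of the total miRNA signal in untreated and 30.6% in MCT-treated lung. Across the 310 miRNAs detected in both, the levels of the 2 arrays had a Pearson r of 0.973; miRNAs are not independent replicates.

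In untreated lung 403 miRNAs (35.3%) exceeded the empty spots, and in MCT-treated lung 316 (27.7%), with 93 detected only in untreated and 6 only in MCT-treated lung. The background was higher on the MCT array. Its empty spots had a median intensity of 253, above the median miRNA spot of 226, whereas the untreated array had 101 for empty and 105 for miRNA spots. With a limit taken from the dim miRNA spots of each array, the order turned to 369 in untreated and 379 in MCT-treated lung. Among miRNAs detected only in MCT-treated lung, the lower bounds were at least 1.67-fold for miR-669b-3p, at least 1.45-fold for the epithelial miR-141-3p, at least 1.41-fold for miR-1930-3p and at least 1.38-fold for miR-224-5p. These bounds hold only for the processing used. Without background correction the estimates of all 4 lay under them, at 1.46-fold for miR-669b-3p, 1.31-fold for miR-141-3p, 1.31-fold for miR-1930-3p and 1.27-fold for miR-224-5p. With the GC trend removed miR-669b-3p had 1.25-fold, miR-141-3p 1.39-fold and miR-224-5p 1.30-fold, and when the arrays were centred on the median the log2 ratios of the 4 were -0.094, -0.39, -0.41 and -0.48. Among those detected only in untreated lung, and under the same limits, miR-5128 was at least 2.29-fold lower in MCT-treated lung, miR-652-5p at least 1.46-fold and miR-681 at least 1.39-fold. Estimates under these bounds were 1.96-fold for miR-5128 without background correction, short of 2-fold, and 2.21-fold with the GC trend removed, where miR-681 had 1.19-fold. Without normalization miR-5128 had 1.41-fold, miR-652-5p 1.21-fold and miR-681 1.10-fold, and scaled by the 5S probes 1.64-fold, 1.41-fold and 1.28-fold. The bound of miR-466c-5p, at least 1.96-fold, rested on 1 spot of 10.34 in untreated lung beside spots of 6.77 and 7.04.

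The comparison addresses which miRNAs differ between 1 sample of MCT-treated and 1 of untreated lung. The arrays do not show whether the treated mice developed pulmonary arterial hypertension. Of the 409 miRNAs detected in either library, 17 were at least 2-fold higher in the MCT library, 9 were at least 2-fold lower and 383 were neither. The higher miRNAs were led by miR-208a-5p, from an intron of the cardiac myosin gene Myh6, at 4.39-fold, miR-100-5p at 3.42-fold and miR-181c-5p at 3.13-fold. The lower ones included miR-223-3p, a miRNA of myeloid cells, at 2.32-fold, and several G-rich miRNAs such as miR-2861 at 2.85-fold. The estimated ratio lay within 1.5-fold for 317 of the detected miRNAs, a range that also held the median estimate for a simulated 2-fold change, 0.47.

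**Figure D1:**
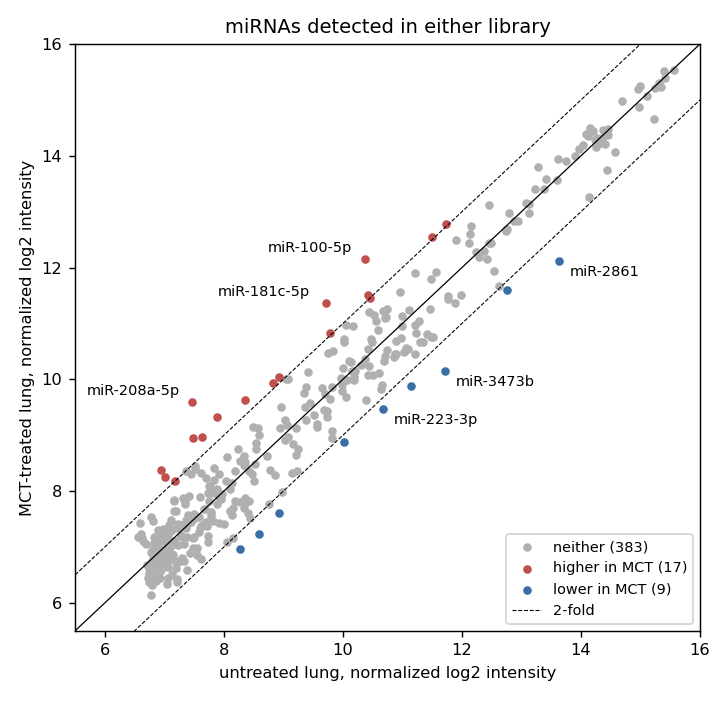
Normalized log2 intensity in untreated lung (x axis) and MCT-treated lung (y axis) of the 409 miRNAs detected in either library, each point the mean of 3 repeat spots on 1 array per group. Red points are the 17 higher and blue points the 9 lower in the MCT library, and dashed lines mark a 2-fold difference.

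The target of miR-208a-5p, GAGCUUUUGGCCCGGGUUAUAC, had a log2 ratio of MCT over untreated lung of 2.14 ± 0.11. Its level was 7.46 ± 0.10 in untreated lung, near the dim end of the array, and 9.60 ± 0.029 in MCT-treated lung. miR-100-5p (AACCCGUAGAUCCGAACUUGUG), a member of the miR-99 and miR-100 family that targets Mtor, was brighter, with 10.38 ± 0.079 against 12.15 ± 0.051 and a log2 ratio of 1.77 ± 0.094. The related miR-99a-5p had a ratio of 0.59 ± 0.028. miR-181c-5p differed by 1.65 ± 0.20, and miR-181d-5p, its neighbour in the genome, by 0.97 ± 0.099, just short of 2-fold. miR-335-5p, from an intron of the imprinted gene Mest, differed by 1.44 ± 0.22, miR-350-3p by 1.28 ± 0.098, miR-5117-5p by 1.09 ± 0.12, and miR-10b-5p, from the Hoxd locus, by 1.11 ± 0.20. Smaller differences past 2-fold were those of miR-146b-5p at 1.05 ± 0.072, miR-342-3p at 1.05 ± 0.11, miR-3963 at 1.00 ± 0.077 and miR-365-3p at 1.00 ± 0.15. The ratio of miR-221-3p, 1.04 ± 1.54, rested on 1 untreated spot of 9.96 beside spots of 12.59 and 12.66. With the median of the spots it was 0.20, so its count as higher ended.

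Among the lower miRNAs, miR-3473b had a ratio of -1.56 ± 0.75, with 1 MCT spot of 9.28 beside 10.59 and 10.56. With the median of its spots the ratio was -1.12. miR-2861, GGGGCCUGGCGGCGGGCGG, had a level of 13.62 ± 0.045 in untreated and 12.11 ± 0.034 in MCT-treated lung, a ratio of -1.51 ± 0.056. miR-133b-5p had a ratio of -1.33 ± 0.16, while the other arm of its hairpin, miR-133b-3p, had 0.79 ± 0.087. miR-680 had -1.36 ± 0.13, miR-3077-5p -1.27 ± 0.12 and miR-705 -1.15 ± 0.075. miR-341-5p had -1.15 ± 0.12, and without normalization its ratio turned to 0.083. miR-223-3p (UGUCAGUUUGUCAAAUACCCCA) had -1.21 ± 0.21, and its other arm, miR-223-5p, had -0.042 ± 0.18 at a level close to background.

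**Figure D2:**
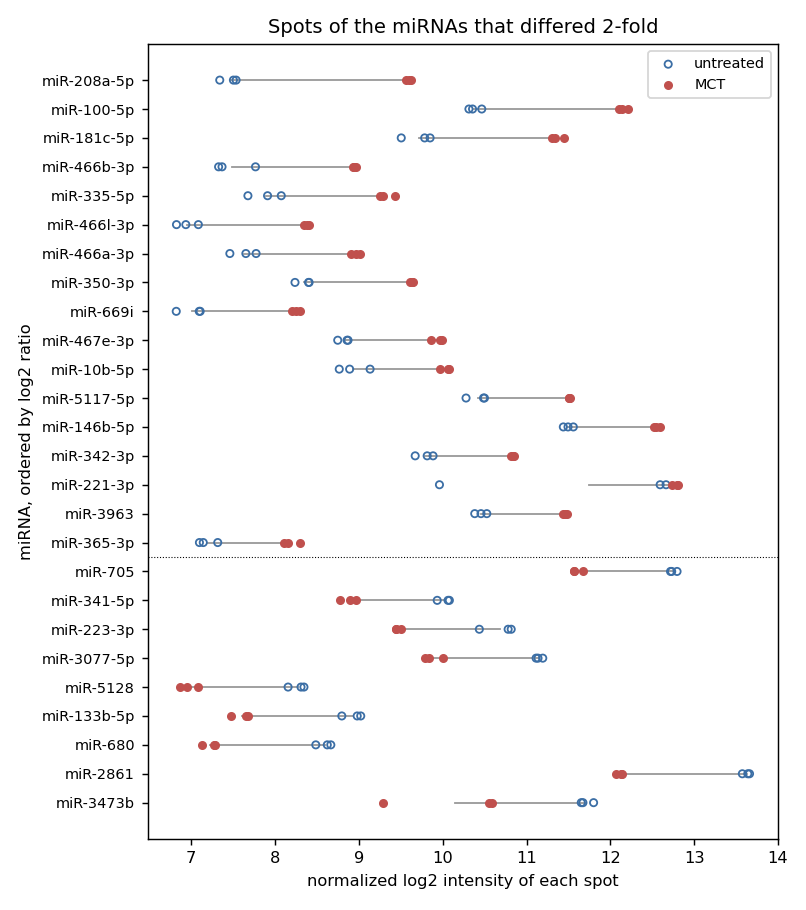
Normalized log2 intensity (x axis) of each repeat spot of the 17 miRNAs higher and 9 lower in the MCT library (y axis, ordered by log2 ratio), with open blue circles for untreated and filled red circles for MCT-treated lung. Grey lines join the means of 3 spots, and single spots lie apart from their repeats for miR-221-3p and miR-3473b.

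The higher and lower miRNAs differed in base composition. The median GC content of the target was 40.9% for the higher, 66.7% for the lower and 50% for the other detected miRNAs. Across the 310 miRNAs detected in both libraries the log2 ratio was lower at higher GC content, with a Spearman's rho of -0.36 over miRNAs, which are not independent replicates. The 60 miRNAs with a GC content over 60% had a median ratio of -0.33, against 0.089 for the 196 between 40% and 60% and 0.039 for the 54 at 40% or less, so the lower ratios lay at the GC-rich end and the medians did not fall steadily. With the GC trend removed, 8 miRNAs were higher and 6 lower, with 9 of the 17 higher and 4 of the 9 lower calls lost. Of the lower, miR-2861 had -0.67, miR-3077-5p -0.61, miR-341-5p -0.62 and miR-705 -0.64. Of the higher, miR-5117-5p had 0.58, miR-467e-3p 0.65, miR-365-3p 0.68, miR-466l-3p 0.80, miR-3963 0.85, miR-221-3p 0.88, miR-146b-5p 0.91, miR-10b-5p 0.95 and miR-342-3p 0.998.

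**Figure D3:**
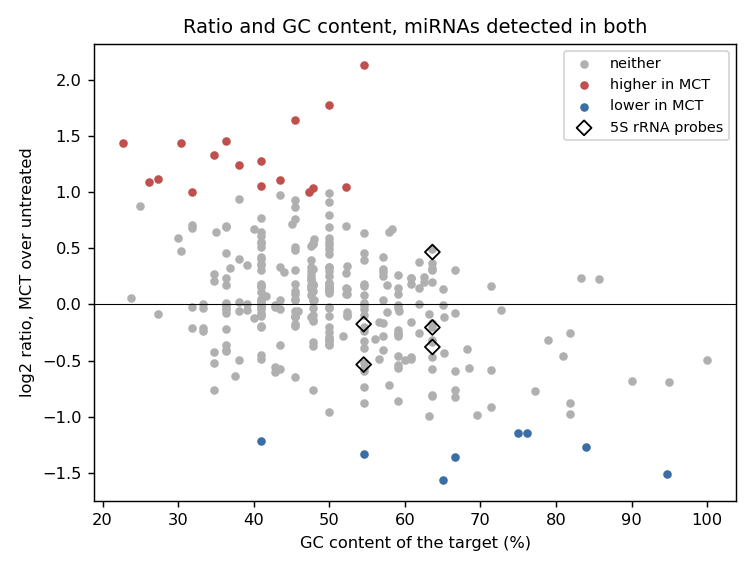
Log2 ratio of MCT over untreated lung (y axis) against the GC content of the target in percent (x axis) for the 310 miRNAs detected in both libraries, with red for higher, blue for lower and grey for neither. Open diamonds are the 5 probes for 5S ribosomal RNA, whose ratios ran from -0.54 to 0.47.

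The counts of higher and lower miRNAs depended on the scaling between the arrays. They were 142 higher and 0 lower without normalization, 97 and 0 when scaled by the 5S probes, 6 and 125 when centred on the median and 17 and 43 when centred on the 75th percentile. These settings moved the median ratio of all detected miRNAs by 0.75, 0.53, -0.64 and -0.31, so each ratio given here is relative to the other miRNAs on the arrays.

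Of the 18 miRNA lists fixed before the data were examined, 4 of the 17 with at least 3 detected members stood apart from random lists of the same size and level, all toward higher values in the MCT library. Most other lists also leaned that way, except red blood cell, let-7 and the miR-297, miR-466, miR-467 and miR-669 families (percentiles 37.4, 17.0 and 13.4). The random lists were not matched on GC content. With the GC trend removed, smooth muscle alone of the 4 still stood apart (percentile 99.1). Centring on the median, which lowers the median of all detected miRNAs as well, put the 4 medians below 0, with percentiles of 98.7 for smooth muscle, which still stood apart, 96.6 for fibroblast and matrix, 85.2 for epithelial and 87.4 for the miR-30 family. Percentiles are given as a description of these 2 libraries. Of the smooth muscle miRNAs, 8 were detected, 2 were higher, 0 lower, and the median log2 ratio was 0.48 (percentile 99.6), or -0.0014 when the arrays were centred on the median. The higher members were miR-100-5p and miR-221-3p. miR-145-3p had 0.70 ± 0.089 and miR-133a-3p 0.64 ± 0.080, both short of 2-fold. miR-145-5p and miR-143-3p, which favour the contractile state of smooth muscle and were its brightest members, had 0.28 ± 0.053 and 0.33 ± 0.41. Without repeat spot 3, which holds the low untreated spot of miR-221-3p, the list's median was 0.21 and its percentile 91.0, so it no longer stood apart. That setting left out spot 3 of every member, so the fall cannot be put on miR-221-3p alone.

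The epithelial list had 12 detected members, none past 2-fold, with a median of 0.40 (percentile 99.5), or -0.22 when centred on the median. Its members with the largest ratios were miR-34b-3p, from a locus active in ciliated cells, at 0.93 ± 0.12, miR-429-3p of the miR-200 family at 0.77 ± 0.017 and miR-34c-3p at 0.69 ± 0.105. The other arms of these miR-34 hairpins had less, miR-34b-5p 0.35 ± 0.18 and miR-34c-5p -0.14 ± 0.071, the latter of opposite sign. miR-200b-3p had 0.46 ± 0.056, miR-200c-3p -0.039 ± 0.060 and miR-203-3p -0.49 ± 0.098. The median GC content of the detected epithelial miRNAs was 42.2%, and with the GC trend removed the list's percentile was 96.1. All 5 members of the miR-30 family, abundant in lung and open to cross-hybridization among near-identical sequences, had positive ratios, with a median of 0.31 (percentile 99.1), or -0.63 and -0.29 when centred on the median or the 75th percentile. miR-30e-5p had 0.36 ± 0.079 and miR-30c-5p 0.34 ± 0.14, the family's median GC content was 43.5%, and with the GC trend removed its percentile was 95.5.

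The fibroblast and matrix list had 12 detected members, none past 2-fold, with a median of 0.25 (percentile 97.6), or -0.16 when centred on the median. miR-199a-5p had 0.70 ± 0.086, miR-29c-3p, of the collagen-repressing miR-29 family, 0.69 ± 0.11, miR-148a-3p 0.54 ± 0.18 and miR-199b-5p 0.54 ± 0.16. In contrast miR-29a-3p had -0.20 ± 0.050 and miR-214-3p -0.28 ± 0.048, and the profibrotic miR-21-5p had 0.23 ± 0.093. The list's median GC content was 43.2%, and with the GC trend removed its median was 0.083 and its percentile 84.6.

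**Figure D4:**
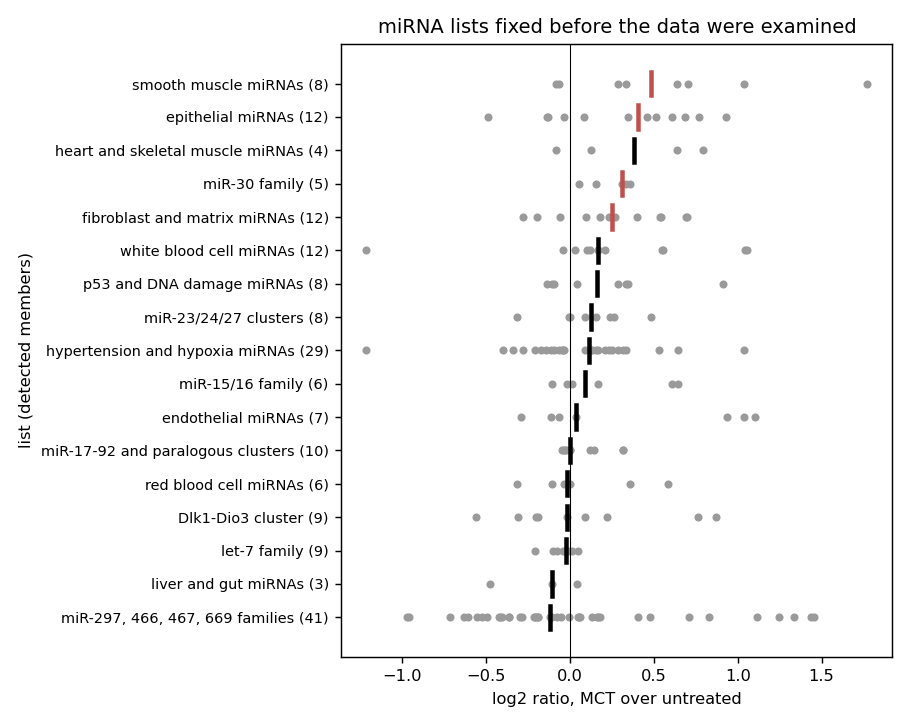
Log2 ratio of MCT over untreated lung (x axis) of the detected members of each miRNA list (y axis, number detected in parentheses), with grey points for single miRNAs and a bar for the median. Red bars mark the 4 lists that stood apart from random lists, smooth muscle, epithelial, miR-30 family, and fibroblast and matrix, whose medians lay below 0 when the arrays were centred on the median, where smooth muscle alone of the 4 still stood apart.

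The miRNAs most studied in pulmonary hypertension and hypoxia did not stand apart. Of 38 listed, 29 were detected, 1 was higher (miR-221-3p, on 1 spot), 1 lower (miR-223-3p), and the median was 0.11 (percentile 92.8). miR-322-5p had 0.65 ± 0.067, miR-125a-5p 0.53 ± 0.30, the hypoxia-induced miR-210-3p -0.34 ± 0.11 and miR-17-5p 0.12 ± 0.046. miR-26a-5p had 0.11 ± 0.086, miR-451 -0.038 ± 0.035 and miR-126-3p -0.12 ± 0.12. Of the 7 endothelial miRNAs, all detected, 2 were higher, miR-10b-5p and miR-221-3p, and the median was 0.038 (percentile 66.8). This depended on miR-126-5p, which was not above the empty spots in MCT-treated lung. Over the 6 detected in both libraries the median was 0.49 and the list stood apart (percentile 99.1). That median lay between miR-10a-5p and miR-218-5p. It also rested on the 1 low spot of miR-221-3p, whose ratio with the median of its spots, 0.20, falls between those 2. miR-218-5p had 0.94 ± 0.22, miR-10a-5p 0.038 ± 0.051 and miR-222-3p -0.067 ± 0.057.

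Markers of blood cells gave a mixed picture. Of the 12 detected white blood cell miRNAs, 2 were higher, miR-146b-5p, a feedback inhibitor of NF-κB signalling, and miR-342-3p, and 1 was lower, miR-223-3p. The list's median was 0.17 (percentile 94.5), and it stood apart with cyclic loess, with no detection filter and with the authors' values (percentiles 97.9, 98.6 and 99.3). miR-181b-5p had 0.55 ± 0.027, miR-132-3p 0.55 ± 0.16, miR-155-5p 0.21 ± 0.095, miR-150-5p 0.17 ± 0.077 and miR-146a-5p 0.028 ± 0.062. None of the 6 detected red blood cell miRNAs passed 2-fold, and their median was -0.019 with a mean of 0.080 (percentile 37.4). miR-16-5p had -0.11 ± 0.033, and the probe named miR-3107-5p, whose sequence is also that of the erythroid miR-486-5p, had -0.31 ± 0.047.

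Among lists of other tissues, 4 heart and skeletal muscle miRNAs were detected, none past 2-fold, with a median of 0.38 (percentile 84.5). miR-133b-3p had 0.79 ± 0.087, miR-206-3p 0.12 ± 0.12 and miR-1a-3p -0.086 ± 0.076. The 3 detected liver and gut miRNAs had a median of -0.11 (percentile 53.6), among them miR-192-5p at -0.11 ± 0.15. Of the brain and endocrine list only miR-128-3p was detected, at 0.52 ± 0.17. The p53 and DNA damage list had 8 detected members, none past 2-fold, and a median of 0.16 (percentile 83.7). Its largest ratio was that of the p53 target miR-34a-5p, 0.91 ± 0.032.

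Of the miR-297, miR-466, miR-467 and miR-669 families, listed by the start of their names for the cluster in an intron of the mouse gene Sfmbt2, 41 miRNAs were detected, 5 were higher and 0 lower. By name 24 of the 41 were placed in that cluster, 8 elsewhere in the genome, and 9 could not be placed. The higher ones were miR-466b-3p at 1.45 ± 0.24, miR-466l-3p at 1.43 ± 0.13, miR-466a-3p at 1.33 ± 0.17, miR-669i at 1.25 ± 0.17 and miR-467e-3p at 1.11 ± 0.097. With the GC trend removed 3 of these were still higher, miR-466l-3p at 0.80 and miR-467e-3p at 0.65 were not, and miR-466i-5p was lower at -1.07. The probes of miR-466b-3p and miR-466a-3p match the mature sequences of other miRNAs of these families as well, and the families are open to cross-hybridization. The 23 bases of the miR-466a-3p target contain the 22 of miR-466b-3p, so these need not be separate results. In untreated lung miR-466l-3p (6.95) and miR-669i (7.01) lay near the lowest level of a detected miRNA, 6.68. The brightest, miR-466i-5p, whose gene lies outside the cluster, had -0.96 ± 0.037, and miR-669p-3p had -0.63 ± 0.063. The list's median was -0.12 and its mean 0.0092, which differ in sign (percentile 13.4). Its median GC content was 37.5%, and with the GC trend removed its median was -0.34 (percentile 0.03).

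The medians of the remaining groups lay near 0 in the normalization used. The let-7 family had 9 detected members, none past 2-fold, and a median of -0.027 (percentile 17.0). This depended on the scaling: its median was -1.16 when centred on the median, with let-7a-5p at -1.20, let-7f-5p at -1.17 and let-7c-5p at -1.21, and -0.82 when centred on the 75th percentile. With either centring, without normalization and with 5S scaling the family stood apart toward lower values (percentile 1.74). This is 1 result, as these settings differ by a constant. A constant also leaves in place any difference between the arrays that varies with intensity, and let-7 miRNAs were among the brightest. Quantile normalization and cyclic loess, which scale by intensity, gave percentiles of 17.0 and 3.45, where the family did not stand apart. The low percentile therefore cannot be put on the let-7 family alone. The miR-17-92 and paralogous clusters had 10, a median of -0.0007 and a mean of 0.075, which differ in sign (percentile 57.1), with miR-92a-3p at 0.32 ± 0.036. The miR-15/16 family had 6 with a median of 0.088 (percentile 69.3), among them miR-15a-5p at 0.61 ± 0.093 and miR-497-5p at 0.17 ± 0.071. The miR-23/24/27 clusters had 8 with a median of 0.12 (percentile 79.7), among them miR-23b-3p at 0.26 ± 0.10 and miR-24-2-5p at -0.32 ± 0.096. Of 54 measured miRNAs of the imprinted Dlk1-Dio3 cluster 9 were detected, with a median of -0.020 and a mean of 0.072 (percentile 83.7). miR-494-3p had 0.87 ± 0.22 and miR-485-3p -0.56 ± 0.14. When the arrays were centred on the median, the medians were -0.26 for the miR-17-92 and paralogous clusters, -0.30 for the miR-15/16 family, -0.80 for the miR-23/24/27 clusters and -0.99 for the Dlk1-Dio3 cluster, none of which stood apart.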

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

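All tests of explanations in this part were chosen after the result was seen, and so were the GC trend removal and the local background. A control probe, Ctr09-3M10, stood out although it belongs to no comparison: its log2 ratio was 1.33 ± 0.35 (2.52-fold) over 4 spots, above the empty spots, while Ctr09-3P had 0.034 ± 0.10. The spots of Ctr09-3M10 did not overlap between the arrays, so a probe of no miRNA met the size and spot rules of the calls.

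The ratio was lower at a higher GC content of the target, with a Spearman's rho of -0.36 over 310 miRNAs, and with -0.349 in the authors' own values. Uneven background under dim spots is argued against by a rho of -0.34 (bootstrap 95% interval -0.468 to -0.21) among the 205 miRNAs above the median level. With the mean trend over GC content removed, 13 of the 26 called miRNAs kept a 2-fold difference, although miR-2861 and miR-705 did not. That mean trend therefore does not give all the calls. An effect of base composition beyond it cannot be excluded, since the trend lay mostly with G (rho -0.42, against 0.119 for C) and the removal used G and C together. A difference in hybridization or washing between the arrays may account for it, since the trend was also present among miRNAs of the same genomic cluster, with a rho of -0.33 against -0.195 to 0.19 in 2000 permutations within clusters, and of -0.29 against -0.237 to 0.199 without the largest cluster. RNA quality, the age of the mice and the treatment itself were not tested apart from this and stay open, as each group has 1 array.

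The largest ratio, that of miR-208a-5p, raised the question of heart tissue in the MCT sample. Against it, miR-208a-3p, miR-208b-3p and miR-499-5p were all below the median empty spot in MCT-treated lung, and the heart miRNA miR-1a-3p had a ratio of -0.086 ± 0.076, while miR-133a-3p and miR-133b-3p, at 0.64 and 0.79, went the other way. The GC trend does not account for it, since the ratio was 2.15 with the trend removed. A signal from another transcript at this probe, or a treatment effect on this arm alone, may remain as explanations, and neither was tested.

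miR-223-3p had a ratio of -1.21, unlike the other white blood cell miRNAs: 10 of these 11 had positive ratios, with a median of 0.17 (bootstrap 95% interval 0.104 to 0.552), relative to the other miRNAs on the arrays. The interval takes these miRNAs as independent, which arms of 1 hairpin are not. The whole list had 12 of 17 members detected, with miR-142-3p and miR-142-5p not among them. Its median was -0.51 when centred on the median and -0.17 at the 75th percentile. Relative to the other miRNAs the list was not low (percentile 90.1), so its detected members gave no sign of fewer white blood cells of all kinds. The list cannot exclude this, since the sign of its median depended on the scaling and some of its members were not detected. A shift between kinds of white blood cell could also give the low miR-223-3p and was not tested. An error of single probes cannot be told apart from a true difference with 1 array per group. Of the 41 pairs of arms 1, that of miR-133b, lay as far apart as the ratio of miR-223-3p. The control probe Ctr09-3M10, at 1.33 ± 0.35, also lay farther from 0 than miR-223-3p. The 5 probes for 5S ribosomal RNA had smaller ratios, from -0.54 to 0.47.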

How the results depend on the processing

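GC trend removal, local background and detection from dim spots were added after the data were seen. Scaling had the largest effect on the counts: without normalization 142 miRNAs were higher and 0 lower, scaled by the 5S probes 97 and 0, centred on the median 6 and 125, and centred on the 75th percentile 17 and 43. By construction these settings differ from each other by 1 constant for all miRNAs. The GC trend removal gave 8 higher, local background 37 higher and 36 lower, an offset of 16 gave 19 lower, the authors' values 16 lower, and a 1.5-fold threshold 46 and 44 by its construction; for the rest of these the cause was not tested. In the other settings the counts stayed within 1.5 times of 17 and 9, and detection within 1.5 times of 403 and 316. The scalings other than none, the background settings, the median of the spots and the authors' values, 9 settings in all, each kept the same 6 of the higher calls (miR-100-5p, miR-181c-5p, miR-208a-5p, miR-335-5p, miR-350-3p and miR-466b-3p) while 5S scaling left 0 lower calls by its upward shift, and 6 of the 9 lower calls were kept in each of the other 8 (miR-133b-5p, miR-223-3p, miR-2861, miR-3077-5p, miR-3473b and miR-680). miR-341-5p turned to 0.083 without normalization. Centring on the median moved the median ratio of all detected miRNAs by -0.64 and put the list medians at -0.0014 (smooth muscle), -0.16 (fibroblast and matrix), -0.22 (epithelial) and -0.63 (miR-30 family), the last also at -0.29 at the 75th percentile; their percentiles were then 98.7, 96.6, 85.2 and 87.4, so only smooth muscle still stood apart. Of 18 settings, smooth muscle stood apart in 13, epithelial in 12, the miR-30 family in 9, and fibroblast and matrix in 3. Among these, no normalization, either centring and 5S scaling give a list the same percentile by construction and so repeat 1 result. Lists that did not stand apart did so in some settings. The endothelial list did over members detected in both libraries (median 0.49, percentile 99.1), which also rested on the 1 low spot of miR-221-3p. The white blood cell list did with cyclic loess, no detection filter and the authors' values (97.9, 98.6 and 99.3). The list of miR-297, miR-466, miR-467 and miR-669 families did with the GC trend removed (0.03). The let-7 family did toward lower values (1.74) without normalization, with either centring and with 5S scaling, which is 1 result by construction. These settings leave in place any difference between the arrays that varies with intensity. Of 1246 values of named miRNAs under alternatives, 731 moved by less than the spot spread, 514 by more, and 1 value of a called miRNA changed sign. Sign changes of miRNAs that were not called were not counted apart, such as that of miR-141-3p to -0.39 when centred on the median. Not run were subtraction of a measured local background and 6 background standard deviations, since the tables used here hold neither quantity. No paired analysis was possible because each group has 1 array. The high background of the MCT array limits what can be said of dim miRNAs.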

Other observations

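The tests in this part were chosen after the results were seen. Within the miR-297, miR-466, miR-467 and miR-669 families the ratios followed the level: the 41 detected miRNAs had a Spearman's rho of -0.69 between mean level and ratio, against 0.13 over the 409 miRNAs detected in either library. Among the 24 placed by name in the Sfmbt2 cluster rho was -0.59, and 3 of the 5 higher ones were among them. The 5 higher ones all had mean levels of 9.38 or less, while the bright miR-466i-5p, from outside that cluster, had -0.96. An impression that the 3p arms of these families were higher than the 5p arms did not hold, with median ratios of -0.20 over 21 3p arms and -0.057 over 11 5p arms. Neighbours in the genome also differed: miR-221-3p and miR-222-3p had 1.04 (on 1 spot) and -0.067, while miR-2861 and miR-3960, both very GC-rich, had -1.51 and -0.69.

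The base behind the GC trend was mostly G, with a Spearman's rho of -0.42 for the G content, against 0.119 for C, 0.155 for A and 0.30 for U. The position on the chip gave -0.040. The 5 probes along 5S ribosomal RNA, which report 1 molecule, had ratios from -0.54 to 0.47, a range of 1.00, and 107 of the 409 detected miRNAs had a ratio at least as large in size as the largest of these.

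A hypothesis that shared transcripts set part of the ratios was tested on 138 miRNAs in 46 genomic clusters or arm pairs. The standard deviation of the ratios within clusters was 0.44, at the edge of the shuffled values, whose 2.5th percentile was 0.442 and median 0.488, and 2.19% of 10000 shuffles were as low. Without the largest cluster it was 0.386 against 0.419 and 0.471. This is consistent with a part of the ratios being shared by neighbours, which may be transcription or similar probe sequences. Over the 41 pairs of arms of the same hairpin the Pearson r was 0.0988 and Spearman's rho 0.14, so the arms gave little sign of it.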
